A study of Rattus norvegicus with 24 samples.

How the data were processed

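Testis RNA of male Fisher 344 rats was measured on Affymetrix Rat230_2 arrays, 1 array per sample, in 24 samples that fall into 6 groups of 4. Per the labels' protocols, total RNA was biotin-labelled by the manufacturer's protocol, and the submitters' processing notes name GCOS 1.0, the array maker's software. The deposited values are linear probe-set intensity, all positive, with no detection calls, and the values show that each array was scaled to the same 2% trimmed mean, between 500.135 and 500.194. The summarization algorithm behind the deposited intensity is not given in the sources used here. Per the labels, RNA was extracted with Trizol and a micro clean-up kit at gestational day 20 (GD20). At postnatal day 35 (PND35) a column kit was used on 14 arrays and Trizol with clean-up on 2 arrays, 1 in each of the groups with fetal oil.

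The following choices were made before the data were examined: the groups, the comparisons and their tests, the alternatives not named below as added, the 24 gene lists and the rule for which genes are named. A pseudocount of 16 was added to each intensity before log2, and 12.1% to 19.4% of the probe sets of an array had an intensity under 16. Fold changes are therefore on the log2(intensity + 16) scale, which understates the change of dim genes. Arrays were left as deposited at GD20, where the medians of the log2 values spanned 0.079, and each was centred on its median at PND35, where they spanned 0.155, since 0.1 had been set as the limit. The table holds 31099 probe sets, of which 57 manufacturer's controls were left out of the tests and 31042 were tested with no further filter. Probe sets were named from the platform's annotation: 20826 have 1 gene symbol, 436 have several and were not named, and 9780 have none there. Of the named probe sets, 20758 matched the gene table by gene number and 0 symbols had to be updated. Where a gene has several probe sets, the one with the highest mean over the arrays of that age stands for it, which gives 14217 genes. Of the genes set to be named whatever their values, 3 had no probe set with a single symbol and are not reported here.

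Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the 31042 probe sets and a threshold of 0.05. The 8 GD20 arrays were fitted on their own, and the 16 PND35 arrays in 1 fit with 4 groups that share an estimate of the spread. The 6 contrasts are fetal DBP against oil at GD20, postnatal DBP against oil after fetal oil and after fetal DBP, fetal DBP against oil before postnatal oil and before postnatal DBP, and the interaction of both exposures. Errors of log2 fold changes are the moderated standard errors of that fit (SE), and errors of intensities are standard deviations over 4 arrays (SD). The gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes and beside it with an estimated correlation, on 1 probe set per gene, and adjusted over the 24 lists within a contrast. That makes 144 tests of lists. fry, a rotation test that does not compare a list with other genes, was an alternative. RNA integrity numbers from the labels were compared by an exact permutation test, two-sided, in the 5 pairs of groups.

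The lists cover steroidogenesis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and other PPAR targets, immediate early genes, inflammation and cytokines, apoptosis and p53 targets, glucocorticoid response, NRF2 and xenobiotic metabolism, heat shock and the unfolded protein response, cell cycle, Sertoli cell junctions and cytoskeleton, and genes tied to retinoic acid or to fetal phthalate exposure in the literature. Marker lists cover Sertoli cells, gonocytes and spermatogonia, spermatocytes, spermatids, peritubular myoid cells, endothelium, macrophages and leukocytes, blood, epididymis, adrenal gland and kidney, and adipose tissue. Genes are named per contrast by 4 rules. These take the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays do not overlap between the groups, up to 4 genes past the threshold per list, a short set named whatever its values, and the 5 smallest p where fewer than 5 genes pass. Probe sets without a single symbol were not eligible, and predicted LOC and RGD symbols were passed over among the largest changes. Largest rises and falls below are therefore those among the genes so named. A gene named outside these rules, or given as a further member of a list, was chosen after its values were seen.

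Alternatives were quantile normalization, centring on the 75th percentile, a filter on dim probe sets, eBayes without the trend, array weights, pseudocounts of 1 and 64, the extraction method and the RNA integrity number as covariates, leaving out the 2 Trizol arrays, fits of only the 8 arrays compared, adjacent pup numbers as a block, leaving out the pooled control array, and leaving out each array in turn. Chosen after seeing the data were median centring at GD20 and no centring at PND35, the contrast of fetal DBP against oil averaged over both postnatal groups, the ratio of the 3' to the 5' GAPDH control as a covariate, leaving out dams 19 and 21 together, leaving out arrays for the agreement between contrasts, and the class of spike-in signal. For that class, the mean log2 signal of the poly-A spike-in controls Dap, Lys, Phe and Thr, which are added to the RNA before labelling, was taken per array and the arrays of an age were parted at the widest gap. No labelling date or batch is stated in the labels used here.

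The fit was tested on simulated data with the mean and pooled spread of each real probe set and 50 probe sets changed by each of 4 sizes. Noise was drawn independently per probe set, with the same spread in all groups. The shares recovered therefore do not cover correlated genes or groups of unequal spread, as at GD20. Among 31042 probe sets at GD20 it recovered 62% of changes of log2 1 and 92% of changes of log2 2. For the contrast of postnatal DBP after fetal oil these shares were 52% and 98%, and for the interaction 34% and 70%. Changes of log2 0.5 were mostly missed, with 32% recovered at GD20, 10% after fetal oil and 6% for the interaction. Arrays give no counts, so the number of arrays limits the precision. The replicates carry the numbers of different dams at GD20 and of different pups at PND35. The litter of each pup is not stated in the labels used here, so pups of 1 litter cannot be ruled out among replicates.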

Results

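Gene expression was measured in the testis of male Fisher 344 rats after exposure to dibutyl phthalate (DBP), a plasticizer that disturbs development of the male reproductive tract in rats, in utero, around puberty, or at both times. Dams received corn oil or 50 mg/kg DBP by gavage once a day from gestational day 12 to 20. Fetal testes were taken on GD20 from 4 oil and 4 DBP dams, and 1 of the oil arrays, that of dam 2, is labelled as a pool of several samples. The DBP samples of GD20 were taken 6 hours after the last dose, and no interval is recorded here for the oil samples. Effects of the last dose and of the earlier doses therefore cannot be told apart at GD20. Offspring received a second gavage of corn oil or 500 mg/kg DBP on PND35 and their testes were taken 6 hours later. This gives 4 groups of 4 pups, named here by fetal and then postnatal exposure: oil-oil, oil-DBP, DBP-oil and DBP-DBP. The median probe-set intensity of an array lay between 164.4 and 174.5 at GD20 and between 100.8 and 114.1 at PND35.

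Replicates were closest among the fetal controls. Over probe sets well above background, the standard deviation of log2 differences between arrays of a group was 0.14 to 0.155 among GD20 oil arrays and 0.208 to 0.301 among GD20 DBP arrays. At PND35 it ranged from 0.149 for the closest pair of DBP-DBP arrays to 0.352 for the farthest pair of oil-DBP arrays. On the first principal component, which held 53.2% of the variance at PND35, all 8 arrays with postnatal oil lay between -31 and -22.2 and all 8 with postnatal DBP between 14 and 42.5. RNA integrity numbers lay between 8.2 and 8.9. The mean was 8.75 in GD20 oil and 8.70 in GD20 DBP (exact permutation test, two-sided, p = 0.657, adjusted p = 0.821). Postnatal DBP minus oil was 0.175 after fetal oil (exact p = 0.2) and -0.025 after fetal DBP (exact p = 1). Fetal DBP minus oil was 0.35 before postnatal oil (exact p = 0.0571, adjusted p = 0.286 over the 5 pairs of groups) and 0.15 before postnatal DBP (exact p = 0.229). The smallest p that 4 against 4 arrays allow is 0.0286.

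The poly-A spike-in controls, bacterial transcripts added to the RNA before labelling, fell into separate classes of arrays. At GD20 the DBP arrays of dams 19 and 21 had mean log2 values of 6.60 and 6.44, and the other 6 arrays lay between 8.17 and 8.77. At PND35 all 8 arrays with fetal oil lay between 5.90 and 6.14 and all 4 DBP-DBP arrays lay between 7.31 and 7.53. The DBP-oil group held 2 arrays of each kind, pups 123 and 127 at 5.95 and 6.04 and pups 132 and 134 at 7.52 and 7.5. The comparison of DBP-DBP with oil-DBP therefore follows these classes exactly, and spike-in class and fetal exposure cannot be told apart in it.

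**Figure D1:**
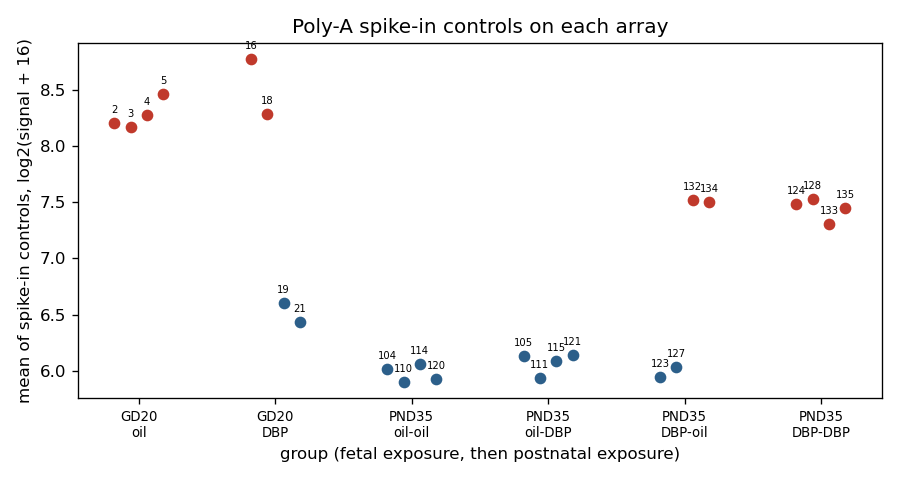
Mean log2(intensity + 16) of the poly-A spike-in controls on each array, by group, with dam or pup numbers beside the points. Red points form the high class and blue points the low class of each age, and the gap between the classes is 1.57 at GD20 and 1.16 at PND35.

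The first comparison asks what daily DBP in utero did to the fetal testis at GD20. Among the genes named by the rules, the largest rise was in Stc1, the secreted hormone stanniocalcin. Its intensity was 1120 ± 450 after DBP against 306 ± 22.1 after oil (SD, n = 4 each), a log2 fold change of 1.74 ± 0.20 (SE, adjusted p = 0.00323). Both other probe sets of Stc1 passed in the same direction. Smpx, a small cytoskeletal protein of striated muscle, rose by 1.54 ± 0.16, and Testin, a protein secreted by Sertoli cells, by 1.54 ± 0.24. B3galt5, a galactosyltransferase of glycan chains, fell by 1.83 ± 0.24, from 82.3 ± 9.49 to 12.3 ± 7.75. Ccnd2, the cyclin D2 of the G1 phase, fell by 0.87 ± 0.16, from 7730 ± 293 to 4350 ± 1110. In all, 137 probe sets passed the threshold, 65 higher (48 genes) and 72 lower (45 genes), and 3652 had an unadjusted p under 0.05 where chance gives 1552.

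Other genes with large rises were Nppc, the C-type natriuretic peptide (1.38 ± 0.20), Lrp2bp (1.23 ± 0.22), Smlr1 (1.21 ± 0.21), Gnrhr, the receptor of gonadotropin-releasing hormone (1.12 ± 0.15), Nr4a1, an orphan nuclear receptor and immediate early gene (1.06 ± 0.19), Chchd4l1 (0.95 ± 0.11) and Hao2, a peroxisomal oxidase (0.89 ± 0.11). Lrp2bp stayed dim, at 27.7 ± 7.38 against 2.52 ± 1.26. The other falls named as largest were Dennd6b (-1.33 ± 0.24), Gadd45g, a stress-induced regulator of growth arrest that also acts in male sex determination (-0.75 ± 0.11), Bsn, the synaptic protein bassoon (-0.74 ± 0.10), and Greb1 (-0.74 ± 0.10). They also include Cacna1h, a T-type calcium channel (-0.70 ± 0.13), Rcor1, a corepressor (-0.69 ± 0.12), Naglu, a lysosomal glucosaminidase (-0.67 ± 0.08), and Mical3 (-0.66 ± 0.10). Adjusted p of these 15 genes ranged from 0.0033 to 0.0452, and in each of them all 4 DBP arrays lay beyond all 4 oil arrays. Bsn, Cacna1h, Gnrhr, Greb1, Mical3 and Rcor1 have other probe sets, none of which passed.

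The transcripts of fetal Leydig cell steroidogenesis did not pass the test at GD20. Of 14 steroidogenesis genes 0 passed (2 were higher adjusted over the list alone), and the list's median log2 fold change was 0.06 (limma's camera, adjusted p = 0.538). Star, the carrier of cholesterol into mitochondria, was at 5150 ± 1180 against 4860 ± 412 (log2 0.06 ± 0.14, adjusted p = 0.909). Cyp11a1 was at -0.05 ± 0.08, Cyp17a1 at 0.07 ± 0.09 and Scarb1, the lipoprotein receptor, at 0.10 ± 0.09. Insl3, the Leydig cell hormone of testicular descent, was at 6020 ± 824 against 7260 ± 313, a log2 difference of -0.28 ± 0.09 that did not pass (adjusted p = 0.265). Kit (-0.21 ± 0.17), Clu (0.28 ± 0.13) and Inha (0.07 ± 0.09) did not pass either.

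Members passed in 4 lists at GD20. Of 15 NRF2 and xenobiotic metabolism genes 2 rose, the aldo-keto reductase Akr1b8 (0.83 ± 0.08, 3580 ± 369 against 2000 ± 45.4) and Cyp1b1 (0.36 ± 0.06), with 4 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.0558). Of 18 genes from the retinoic acid and fetal phthalate literature, Testin and the adaptor Grb14 (0.74 ± 0.11) rose and Crabp2, a retinoic acid binding protein, fell (-0.58 ± 0.09), with 4 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.185). Among 15 fatty acid synthesis genes Fads2 rose (0.42 ± 0.08), while the list's median was -0.05 and its mean 0.02 (camera, adjusted p = 0.703), and among 28 immediate early genes Nr4a1 rose (0.538). In each of both lists 1 gene also passed adjusted over the list alone. The median and mean also differed in sign for the PPAR list (-0.01 and 0.02) and the adrenal and kidney list (-0.08 and 0.06), and neither passed (0.974 both). The peritubular myoid list passed camera with a median of 0.19 (adjusted p = 0.0159), though 0 of its 13 members passed singly and 3 did adjusted over the list alone. With an estimated correlation its adjusted p = 0.555. The spermatid list also passed, with a median of 0.59 over 23 genes and 0 members past the threshold (adjusted p = 0.012, and adjusted p = 0.762 with an estimated correlation). Its signal stood out on the DBP array of dam 21, where the protamine Prm1 was at 1470 against 46 ± 16.7 in the oil arrays and at most 116 on the other DBP arrays, and without that array the list's median was 0.13 (adjusted p = 0.486). Without it the macrophage list (0.15, adjusted p = 0.0186, against 0.0558 with it) and the NRF2 list (0.15, adjusted p = 0.0186) passed. Both were lost with an estimated correlation (adjusted p = 0.852 and adjusted p = 0.378).

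Leaving out the oil array of dam 2, 3, 4 or 5 gave 42, 41, 36 or 29 probe sets, and leaving out the DBP array of dam 16 gave 74. A fit without the intensity trend gave 10, and a filter on dim probe sets gave 210. The share of higher among the called was 47.4%, and 61.3% with centring on the 75th percentile or 67.8% with median centring, but 38% without dams 19 and 21. With the spike-in class as a covariate 96 probe sets passed, 50 of them among the 137, and without dams 19 and 21 there were 166, with 75 of them among the 137. Of the 25 named genes that passed, 12 still passed with the class as a covariate and all 25 had the same sign. The 13 that did not were Cacna1h, Crabp2, Dennd6b, Fads2, Gadd45g, Grb14, Lrp2bp, Mical3, Nppc, Nr4a1, Rcor1, Smlr1 and Testin. With it 2 NRF2 genes were higher, and 0 genes of the retinoic acid, fatty acid synthesis and immediate early lists passed. The blood list, with 0 of 8 genes past the threshold and a median of 0.35 before (camera, adjusted p = 0.265), then had 2 higher and a median of 0.87. Over 19 alternatives, which count leaving out dam 2 both as the pooled array and as a single array, only B3galt5 kept its call in each that tested it. B3galt5 was too dim for the filter on dim probe sets, so that alternative did not test it. The call ended only without the intensity trend in 8 genes, Akr1b8, Chchd4l1, Gnrhr, Greb1, Hao2, Naglu, Smpx and Stc1. It ended in 10 to 14 alternatives in 9 genes, in each case also without any 1 of the 4 oil arrays: Cacna1h, Ccnd2, Dennd6b, Fads2, Lrp2bp, Nr4a1, Rcor1, Smlr1 and Testin.

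The next comparison asks how the peripubertal testis of animals without fetal exposure responded within 6 hours to 500 mg/kg DBP. On the log2 scale with the pseudocount, the chemokines Cxcl1 and Ccl2 had the largest rises among the named genes. As a plain ratio of mean intensity, Calcb rose more than Ccl2, from 10.2 to 889. Cxcl1, a neutrophil chemokine, went from 8.99 ± 7.58 in oil-oil to 3540 ± 659 in oil-DBP (SD, n = 4 each), a log2 fold change of 7.11 ± 0.29 (SE, adjusted p = 4.94e-12). Ccl2, the main monocyte chemokine, rose by 5.21 ± 0.32, from 40.1 ± 30.3 to 1950 ± 615. Fos, a subunit of the AP-1 transcription factor, rose by 4.87 ± 0.27, from 21.8 ± 15.2 to 1080 ± 112, and Egr1, a zinc finger transcription factor, by 3.84 ± 0.18, from 212 ± 36.7 to 3370 ± 231. In all, 2770 probe sets passed, 1481 higher (975 genes) and 1289 lower (956 genes), and 7485 had an unadjusted p under 0.05 where chance gives 1552. On the log2 scale with the pseudocount, which shrinks changes of dim probe sets, 678 rose and 161 fell by at least 2-fold, and 53 rose and 0 fell by at least 8-fold. As plain ratios of mean intensity 794 rose and 187 fell by at least 2-fold, and 113 rose and 5 fell by at least 8-fold.

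**Figure D2:**
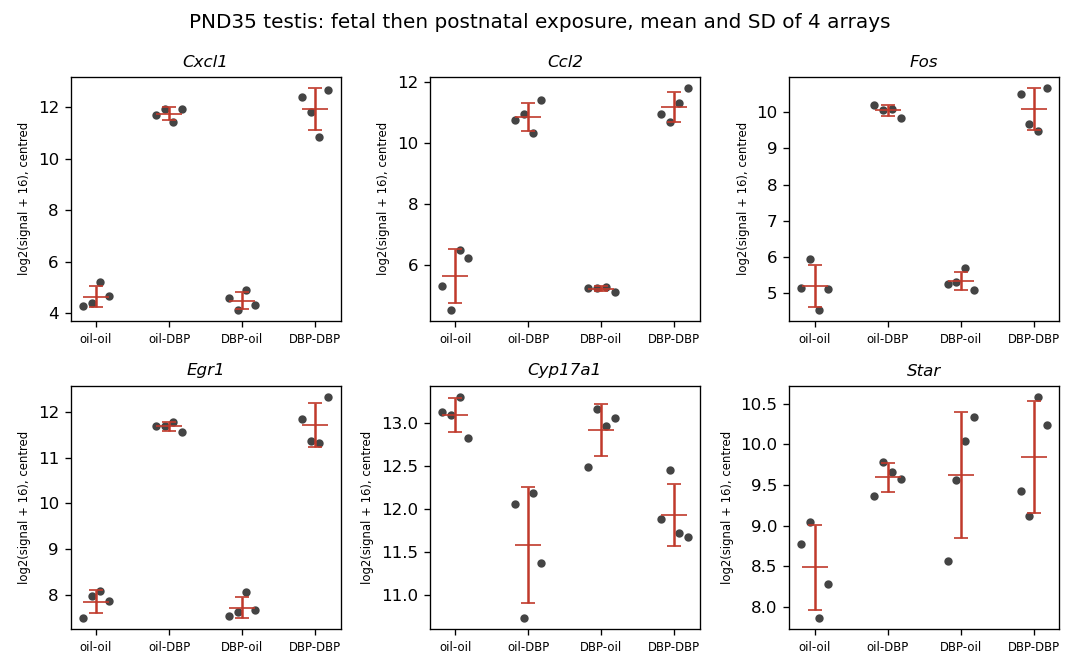
Log2(intensity + 16), centred per array, of 6 genes in the 4 PND35 groups, with points for arrays and red marks for the mean and SD of 4 arrays. Cxcl1, Ccl2, Fos and Egr1 lie higher on all 4 arrays of each group with postnatal DBP than on any array with postnatal oil, and Cyp17a1 lies lower, while the ranges of Star overlap between DBP-oil and DBP-DBP.

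Of 28 immediate early genes 24 rose and 0 fell (24 also adjusted over the list alone), with a median log2 fold change of 2.02 (camera, adjusted p = 5.07e-45, and 3.71e-05 with an estimated correlation). Besides Fos and Egr1 they include Egr2 (3.48 ± 0.26), Ccn1, a matricellular protein (3.26 ± 0.19), Zfp36, which destabilises cytokine messenger RNA (3.12 ± 0.13), Atf3, a stress-induced transcription factor (2.75 ± 0.29), Junb (2.76 ± 0.21), Myc (2.73 ± 0.23) and Jun (1.57 ± 0.14). Of 27 inflammation and cytokine genes 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 2.21 (camera, adjusted p = 3.48e-28, and 0.0016 with an estimated correlation). Ccl20 rose by 4.23 ± 0.44, Ccl7 by 4.21 ± 0.24, Il6 by 3.31 ± 0.36, the interferon-induced chemokine Cxcl10 by 3.28 ± 0.20, and Il1a by 2.90 ± 0.16. The adhesion molecules Vcam1 and Icam1 rose by 2.73 ± 0.23 and 2.61 ± 0.26. The receptor Tnfrsf12a (4.14 ± 0.22) and Nfkbiz, a nuclear regulator of NF-kB (3.92 ± 0.40), were among the 10 largest rises, with Calcb, a calcitonin gene-related peptide (5.02 ± 0.32), S100a9, a calcium-binding protein of neutrophils (4.58 ± 0.61), and Fst, the activin-binding protein follistatin (3.98 ± 0.30).

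Stress and death-related lists rose in part. Of 21 apoptosis and p53 genes 8 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.32 (camera, adjusted p = 7.05e-04, and 0.0183 with an estimated correlation). The death receptor Fas rose by 1.90 ± 0.35, Tnfrsf1a, the main TNF receptor, by 1.86 ± 0.18, Cflar, an inhibitor of death receptor signalling, by 1.85 ± 0.37, and the cell cycle inhibitor Cdkn1a by 1.69 ± 0.17, while Sesn1 fell (-0.87 ± 0.15). Of 14 glucocorticoid response genes 6 rose and 2 fell (7 and 3 adjusted over the list alone; camera, adjusted p = 8.03e-05, and 0.00508 with an estimated correlation), among them Cebpd (3.26 ± 0.19), Nfil3 (2.46 ± 0.23), Dusp1, a phosphatase that is also an immediate early gene (2.00 ± 0.17), and Ddit4, which fell (-1.06 ± 0.19). Of 15 NRF2 and xenobiotic genes 4 rose and 1 fell (6 and 2 adjusted over the list alone; camera, adjusted p = 0.0214, lost at adjusted p = 0.0558 with an estimated correlation). They include Srxn1 (1.5 ± 0.25), the haem oxygenase Hmox1 (1.01 ± 0.12), Akr1b8 (0.65 ± 0.17) and the glutathione transferase Gsta1, which fell (-0.37 ± 0.10). Of 16 heat shock and unfolded protein response genes 4 rose and 1 fell (5 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.314; median -0.09, mean 0.08). Atf4 rose by 0.69 ± 0.10, Xbp1 by 0.63 ± 0.12, Hspa1a by 0.55 ± 0.15 and Hsph1 by 0.54 ± 0.13.

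Steroidogenic transcripts moved both ways. Of 14 genes 2 rose and 5 fell (2 and 7 adjusted over the list alone), and the list did not pass camera (median -0.32, adjusted p = 0.281). Cyp17a1, which makes androgen precursors, fell by 1.5 ± 0.24, from 8610 ± 1220 to 3370 ± 1370. Cyp11a1, the side chain cleavage enzyme, fell by 1.05 ± 0.32, Nr5a1, the nuclear receptor that drives these genes, by 0.95 ± 0.21, and Scarb1 by 0.74 ± 0.19. Star rose by 1.11 ± 0.33, from 352 ± 125 to 784 ± 121 (adjusted p = 0.0382). Of 20 cholesterol synthesis genes 5 fell and 0 rose (10 and 0 adjusted over the list alone; camera, adjusted p = 0.0032, lost at adjusted p = 0.168 with an estimated correlation), with Dhcr7 (-1.22 ± 0.19), Mvd (-0.47 ± 0.14), Acat2 (-0.46 ± 0.12) and Fdft1 (-0.35 ± 0.10). Of 15 fatty acid synthesis genes Elovl5 rose (0.72 ± 0.11) and 3 fell, Scd (-1.20 ± 0.37), Fads1 (-1.07 ± 0.21) and Fasn (-0.43 ± 0.10), with 1 and 4 adjusted over the list alone (camera, adjusted p = 0.281). Of 24 fatty acid oxidation and PPAR genes 2 rose and 4 fell (3 and 12 adjusted over the list alone; camera, adjusted p = 0.0603). Angptl4, a lipoprotein lipase inhibitor, rose by 1.56 ± 0.18 and the lipid droplet protein Plin2 by 0.84 ± 0.13, while Cpt1a fell by 0.93 ± 0.16 and Acaa2 by 0.51 ± 0.09.

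Among markers of testicular cells, those of peritubular myoid cells rose. Of 13 genes 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.38 (camera, adjusted p = 3.43e-05, and 0.0203 with an estimated correlation), among them the smooth muscle proteins Tagln (0.90 ± 0.12), Cnn1 (0.85 ± 0.14), Tpm1 (0.66 ± 0.10) and Acta2 (0.65 ± 0.14). Of 17 Sertoli cell markers 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera, adjusted p = 0.14), with the homeobox gene Rhox5 (1.12 ± 0.34), the protease Ctsl (1.05 ± 0.21) and Vim (0.38 ± 0.09) higher and Inhbb (-0.86 ± 0.15) and Fabp3 (-0.66 ± 0.13) lower. Of 20 Sertoli junction and cytoskeleton genes 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera, adjusted p = 0.00145, lost at adjusted p = 0.264 with an estimated correlation), including N-cadherin, Cdh2 (1.65 ± 0.16), Nexn (0.73 ± 0.18) and Cldn5, which fell (-0.76 ± 0.16). Of 20 macrophage and leukocyte markers Cd14 (0.92 ± 0.20), Coro1a (0.66 ± 0.16) and Mrc1 (0.35 ± 0.10) rose and Aif1 fell (-0.54 ± 0.14), with 4 and 1 adjusted over the list alone (camera, adjusted p = 0.0227, lost at adjusted p = 0.55 with an estimated correlation). Of 23 spermatid markers 6 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.36 (camera, adjusted p = 4.69e-05, lost at adjusted p = 0.52 with an estimated correlation). Prm2 fell by 0.69 ± 0.20, Tnp2 by 0.58 ± 0.18, Tnp1 by 0.51 ± 0.15 and Prm3 by 0.50 ± 0.16. Each of these 4 calls was lost with quantile normalization, without the intensity trend, without the Trizol arrays and with the RNA integrity number as a covariate. Of 18 genes from the retinoic acid and fetal phthalate literature 6 rose and 1 fell (6 and 3 adjusted over the list alone; camera, adjusted p = 7.05e-04, and 0.0156 with an estimated correlation). Testin rose by 3.73 ± 0.36 and the retinol carrier Rbp4 by 1.12 ± 0.31, and Cyp26b1, which degrades retinoic acid, fell by 1.32 ± 0.26. The other 4 that rose, Egr1, Dusp6, Cxcl10 and Nfil3, are also in the lists above.

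In the remaining lists after fetal oil few members passed. None of 10 gonocyte and spermatogonia markers (camera, adjusted p = 0.933), 12 spermatocyte markers (0.165), 6 epididymis markers (0.778), 8 adipose markers (0.78) or 22 cell cycle genes (0.241) did, and 0 did adjusted over the list alone. Of those, the spermatocyte protein Sycp3 was at -0.10 ± 0.08 (adjusted p = 0.48). In each of 3 lists 1 gene fell: the angiopoietin receptor Tek of 11 endothelial markers (-0.82 ± 0.18; camera, adjusted p = 0.778, with the test pointing up and a median of -0.09), Alas2 of 8 blood genes (-0.36 ± 0.11; 0.933) and Aqp2 of 8 adrenal and kidney markers (-1.74 ± 0.34; 0.608). Outside the lists the largest falls were Tmem229b (-2.54 ± 0.25, from 226 ± 74.2 to 27.1 ± 11.9), the chemokine receptor Cxcr4 (-2.28 ± 0.32), Slc25a45 (-2.04 ± 0.30), Cmtm8 (-1.96 ± 0.27), Zcchc18 (-1.89 ± 0.39), the microtubule protein Camsap3 (-1.80 ± 0.21), Slc7a4 (-1.75 ± 0.43), Mgat4b (-1.65 ± 0.23) and Ddx60 (-1.63 ± 0.36).

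The number of calls after fetal oil moved with single arrays: it was 4607 without pup 105, 1597 without pup 111 and 1716 without pup 121, and 1508 with the RNA integrity number as a covariate or 1541 in a fit of these 8 arrays only. The share of higher among the called was 53.5%. It was 40.9% without pup 105 and 43.7% without dim probe sets, and 69.2% without centring and 70.1% in the fit of these 8 arrays. All 8 arrays are of the low spike-in class. Of the 82 named genes that passed, 59 kept their call in every alternative that tested them, as the filter on dim probe sets left some dim genes untested. Of 22 alternatives, the call ended in 15 for Tnp2 and Prm3, in 14 for Scd and Rhox5, in 13 for Tnp1, in 11 for Fdft1 and Alas2, and in 10 for Prm2, Cyp11a1, Mrc1 and Gsta1. It ended in 9 for Star and Mvd. Some named genes have other probe sets of which none passed, among them Fos, Egr2, Nfkbiz, Fas, Cflar, Star and Nr5a1. For others at least 1 more probe set passed in the same direction, among them Jun, Fst, Cdh2, Cdkn1a, Cebpd and Cxcr4.

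The same dose on PND35 was given to animals exposed in utero, to ask how the acute response runs after the earlier exposure. With the pseudocount, Cxcl1 and Ccl2 again had the largest rises among the named genes. As a plain ratio of mean intensity, Calcb rose about as much as Ccl2, from 7.03 to 810. Cxcl1 went from 6.48 ± 5.39 in DBP-oil to 4320 ± 2080 in DBP-DBP (7.45 ± 0.29, adjusted p = 1.99e-12), Ccl2 from 21.2 ± 1.86 to 2430 ± 876 (5.96 ± 0.32), Fos from 24.7 ± 8.21 to 1140 ± 456 (4.75 ± 0.27) and Egr1 from 196 ± 40.7 to 3530 ± 1260 (4.00 ± 0.18). Cyp17a1 fell by 0.99 ± 0.24, from 7820 ± 1600 to 4000 ± 1020. In all, 1623 probe sets passed, 1131 higher (773 genes) and 492 lower (337 genes), and 4630 had an unadjusted p under 0.05. By at least 8-fold, 56 rose and 0 fell with the pseudocount, and 92 rose and 10 fell as plain ratios of mean intensity.

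Of 28 immediate early genes 22 rose (24 adjusted over the list alone; camera, adjusted p = 1.25e-52, and 1.60e-05 with an estimated correlation), among them Ccn1 (3.45 ± 0.19), Maff (3.42 ± 0.36), Atf3 (3.05 ± 0.29) and Jun (1.52 ± 0.14). Of 27 cytokine genes 18 rose (19 adjusted over the list alone; adjusted p = 1.26e-35, and 5.35e-04 with an estimated correlation), with Ccl20 (4.73 ± 0.44), Ccl7 (4.54 ± 0.24), Cxcl10 (3.79 ± 0.20) and Icam1 (3.20 ± 0.26). Calcb (5.07 ± 0.32), S100a9 (4.32 ± 0.61), Nfkbiz (4.08 ± 0.40) and Serpinb2, an inhibitor of plasminogen activators (4.06 ± 0.44), were among the 10 largest rises. In the apoptosis list 7 of 21 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 5.19e-04, and 0.0133 with an estimated correlation), with Fas (2.01 ± 0.35), Tnfrsf1a (1.84 ± 0.18), Cdkn1a (1.57 ± 0.17) and Cflar (1.39 ± 0.37). Of 14 glucocorticoid response genes 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 2.24e-04, and 0.00784 with an estimated correlation), with Cebpd (3.13 ± 0.19), Dusp1 (2.30 ± 0.17), Nfil3 (2.28 ± 0.23) and Ddit4 (-0.76 ± 0.19). Of 15 NRF2 genes 4 rose (6 adjusted over the list alone; adjusted p = 0.00427, and 0.0179 with an estimated correlation), Srxn1 (1.75 ± 0.25), the cystine transporter Slc7a11 (1.12 ± 0.18), Hmox1 (0.75 ± 0.12) and Txnrd1 (0.38 ± 0.10). Of 18 retinoic acid and phthalate genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 4.27e-04, and 0.00923 with an estimated correlation), with Testin at 3.14 ± 0.36.

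Of 13 myoid markers 7 rose (7 adjusted over the list alone; adjusted p = 3.54e-07, and 0.00923 with an estimated correlation), among them Tagln (1.20 ± 0.12), Actg2 (0.84 ± 0.13), Cnn1 (0.76 ± 0.14) and Tpm1 (0.73 ± 0.10). Of 20 macrophage and leukocyte markers 4 rose, Lyz2 (1.15 ± 0.27), Cd14 (1.14 ± 0.20), Coro1a (0.67 ± 0.16) and Mrc1 (0.50 ± 0.10), with 6 adjusted over the list alone (adjusted p = 1.93e-04, lost at adjusted p = 0.235 with an estimated correlation). The spermatid list had a median of -0.21 with 0 of 23 members past the threshold, 0 also adjusted over the list alone (camera, adjusted p = 0.035, lost at adjusted p = 0.756 with an estimated correlation). Tnp1 was at -0.21 ± 0.15, Vim at 0.24 ± 0.09 and Sycp3 at -0.11 ± 0.08, none past the threshold.

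Other lists after fetal DBP did not pass camera. Of 14 steroidogenesis genes the electron carrier Fdx1 rose (0.37 ± 0.10) and Cyp17a1 and Nr5a1 (-0.95 ± 0.21) fell, with 1 and 3 adjusted over the list alone (adjusted p = 0.705), and Star at 0.22 ± 0.33 did not pass. Of 20 cholesterol synthesis genes Dhcr7 fell (-0.92 ± 0.19), the only one also over the list alone (0.184). Elovl5 rose (0.62 ± 0.11) and Thrsp fell (-1.22 ± 0.35) among 15 fatty acid synthesis genes, with 1 and 2 adjusted over the list alone (0.429). Angptl4 (2.38 ± 0.18) and Plin2 (0.69 ± 0.13) rose and Cpt1a fell (-0.74 ± 0.16) among 24 PPAR genes, with 2 and 2 adjusted over the list alone (0.559; median -0.12, mean 0.02). Inhbb (-0.98 ± 0.15) and Fabp3 (-0.51 ± 0.13) fell among 17 Sertoli cell markers, with 3 higher and 5 lower adjusted over the list alone (0.429). Among 20 Sertoli junction genes Cdh2 (1.75 ± 0.16) and Tpm1 rose and Cldn5 (-0.68 ± 0.16) and Gja1, a gap junction protein (-0.46 ± 0.11), fell, with 4 and 2 adjusted over the list alone (0.0517). Atf4 (0.46 ± 0.10), Hspa1a (0.62 ± 0.15) and Hsph1 (0.46 ± 0.13) rose among 16 heat shock genes, with 4 adjusted over the list alone (0.13). Kdr, an endothelial receptor, rose (1.14 ± 0.22; list 0.541), and Pax8 (-1.48 ± 0.35; epididymis list 0.69) and Aqp2 (-1.18 ± 0.34; adrenal and kidney list 0.617) fell. The gonocyte, spermatocyte, blood, adipose and cell cycle lists had 0 members past the threshold (0.559, 0.559, 0.559, 0.859 and 0.752). Besides Pax8, the largest falls among the named genes were Tmem229b (-2.18 ± 0.25), Nat8f5 (-1.85 ± 0.26), Cxcr4 (-1.73 ± 0.32), Slc25a45 (-1.71 ± 0.30), Avp, the vasopressin gene (-1.67 ± 0.26), Cmtm8 (-1.60 ± 0.27), Camsap3 (-1.49 ± 0.21), Scx (-1.48 ± 0.18) and Tle6 (-1.46 ± 0.29).

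The spike-in class was unevenly spread in this comparison, with all 4 DBP-DBP arrays in the high class against 2 of 4 DBP-oil arrays. With the class as a covariate 935 probe sets passed, 706 higher and 229 lower and 894 of them among the 1623, and between the high arrays alone 874 did, 676 higher and 198 lower. Of the 66 named genes that passed, 51 still did and all 66 had the same sign. The 15 that did not were Aqp2, Cflar, Cldn5, Coro1a, Cyp17a1, Fabp3, Fdx1, Hsph1, Kdr, Lyz2, Nr5a1, Pax8, Thrsp, Tle6 and Txnrd1. With it 21 immediate early, 19 cytokine, 7 myoid and 5 retinoic acid and phthalate genes were higher. Apoptosis genes were then 4 higher and 1 lower, glucocorticoid response genes 4 and 1, and steroidogenesis genes 0 and 0. There were 2 macrophage, 3 NRF2 and 2 heat shock genes higher, and 0 endothelial genes. Of the 66, 46 kept their call in every alternative that tested them, as the filter on dim probe sets left some dim genes untested. Of 23 alternatives, the call ended in 14 for Aqp2 and Thrsp, in 12 for Hsph1 and in 10 for Fdx1.

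The response to postnatal DBP was then set side by side in animals with and without fetal exposure, which share no arrays. Across all 31042 probe sets the log2 fold changes had a Pearson r of 0.612, across the 15521 brighter ones 0.876, and across the 3132 called in either 0.912, with a slope of 0.834 there (genes are not independent replicates). The called probe sets were picked for their change in these same contrasts, which raises r. The slope also depends on which contrast selects. It was 0.813 over the 2770 called after fetal oil and 0.987 over the 1623 called after fetal DBP, so it does not show a weaker response after fetal DBP. Both contrasts called 959 probe sets higher, where independent lists would share 54, and 301 lower, where they would share 20.4, and 1 was called in opposite directions. The interaction, which tests the difference itself, had 0 probe sets past the threshold by limma, with 1466 at an unadjusted p under 0.05 where chance gives 1552 and a smallest adjusted p of 0.672. Cxcl1 differed by 0.34 ± 0.41 between the responses, Ccl2 by 0.75 ± 0.45, Cxcl10 by 0.52 ± 0.29, Icam1 by 0.59 ± 0.36, Atf3 by 0.30 ± 0.42, Egr1 by 0.17 ± 0.25 and Fos by -0.12 ± 0.38. Jun differed by -0.05 ± 0.19, Fas by 0.12 ± 0.50, Cyp17a1 by 0.52 ± 0.34, Star by -0.89 ± 0.46, Tnp1 by 0.30 ± 0.21, Vim by -0.15 ± 0.13 and Sycp3 by -0.01 ± 0.11. The rise of Star after fetal oil and its smaller difference after fetal DBP were not shown to differ. The 5 genes with the smallest p, none of which passed, were RT1-T24-3 (2.38 ± 0.46), Avp (-1.98 ± 0.37), Leng9 (1.89 ± 0.42), Scn1a (1.73 ± 0.36) and Peds1 (-0.84 ± 0.18). As lists, the Sertoli markers differed with a median of -0.15 and 0 of 17 members past the threshold, 0 also adjusted over the list alone (camera, adjusted p = 7.83e-04, lost at adjusted p = 0.703 with an estimated correlation). The spermatid markers differed with a median of 0.19 and 0 of 23 members past it (adjusted p = 0.00511, lost at adjusted p = 0.703 with an estimated correlation).

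The remaining contrasts ask whether fetal DBP left a difference at PND35. In animals that then received oil, 1 probe set passed, that of Tra2a, a splicing regulator, at 547 ± 16.7 in DBP-oil against 269 ± 86.4 in oil-oil (1.01 ± 0.15, adjusted p = 0.0372). It lies outside the naming rule and was chosen after its values were seen. At an unadjusted p under 0.05 there were 2299 probe sets. The 5 other genes with the smallest p did not pass: RT1-T24-3 (-1.75 ± 0.32), Pip5k1a (0.78 ± 0.16), Bst2, an interferon-induced tethering protein (0.63 ± 0.12), Peds1 (0.63 ± 0.13) and the chromatin remodeller Chd4 (-0.42 ± 0.09). Star was at 855 ± 414 against 352 ± 125 (1.14 ± 0.33, adjusted p = 0.334). Cyp17a1 was at -0.17 ± 0.24, Tnp1 at -0.28 ± 0.15, Fos at 0.15 ± 0.27, Cxcl1 at -0.16 ± 0.29, Ccl2 at -0.42 ± 0.32 and Sycp3 at 0.00 ± 0.08. The spermatid list had a median of -0.15 (camera, adjusted p = 0.0209, lost at adjusted p = 0.943 with an estimated correlation), with 0 of 23 members past the threshold, also adjusted over the list alone. The call of Tra2a was lost with the spike-in class as a covariate, among the low arrays, in a fit of the 8 arrays, with the extraction method as a covariate or without the Trizol arrays, without the intensity trend, each with 0 calls. Leaving out any 1 of pups 104, 114, 123, 127, 132 and 134 also gave 0 calls. Without pup 110 there were 9 calls, without pup 120 there were 14, and with the RNA integrity number as a covariate 14.

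In animals that all received DBP on PND35, 0 probe sets passed by limma, with 2791 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0762. The 5 genes with the smallest p, none past the threshold, were the transcription factor Foxo3 (-0.54 ± 0.09), Mroh4 (0.45 ± 0.08), Sncb (-0.42 ± 0.08), Vamp2, a vesicle protein (-0.54 ± 0.11), and Birc2, an inhibitor of apoptosis (0.35 ± 0.07). Cxcl1 differed by 0.18 ± 0.29, Ccl2 by 0.33 ± 0.32, Fos by 0.03 ± 0.27, Egr1 by 0.04 ± 0.18, Cyp17a1 by 0.35 ± 0.24, Star by 0.25 ± 0.33 and Vim by -0.17 ± 0.09. The Sertoli marker list had a median of -0.17, with 0 of 17 members past the threshold, also adjusted over the list alone (camera, adjusted p = 6.86e-05, lost at adjusted p = 0.915 with an estimated correlation). The exposures compared here lie in different spike-in classes. Without pup 105 there were 35 calls and without pup 133 there was 1, and with the RNA integrity number as a covariate 63. Across all probe sets the fetal differences in the contrasts before oil and before DBP had a Pearson r of 0.102, and across the 15521 brighter ones 0.293.

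The fetal differences of GD20 were looked up at PND35. Of the 137 probe sets called at GD20, 62 (45.3%) had the same sign in the contrast of fetal DBP before postnatal oil, which had only 1 call in all. Their log2 fold changes at the different ages had a Pearson r of -0.043, and in the contrast before postnatal DBP the same-sign share was 41.6% and r was -0.297. The spike-in class ran opposite ways there. The low arrays at GD20 were all DBP, while before postnatal DBP the fetal DBP arrays were high and the fetal oil arrays low. A reversal of the fetal differences therefore cannot be told apart from the class. The median size of change was 0.64 at GD20, and signed by the GD20 direction the median change at PND35 before oil was -0.03. The same-sign share was 32.4% without the GD20 DBP array of dam 16 and 36.6% without the oil array of dam 3.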

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

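Both tests of RNA integrity, the test of the extraction method and the test for RNA of older testis were chosen only after the results they address were seen, and the contrast averaged over both postnatal groups was itself added after the data were seen.

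Averaged over both postnatal groups, fetal DBP was tied to 115 probe sets at PND35, 98 higher and 17 lower, led by the kinase Ttk (0.58 ± 0.07, adjusted p = 0.00355), and 2 of 100 random splits within the postnatal groups gave as many, the real one included, with 330 in the highest other. Without the 2 Trizol arrays 0.946 ± 0.076 of their median effect was kept, which argues against the extraction method as the whole cause. Far fewer probe sets then passed, as counted below. With the spike-in class in the fit 0.951 ± 0.114 was kept (0.41 before and 0.39 after), past the bound set beforehand, but that bound decides nothing because the class varies within only 1 group and 1 probe set followed it; the calls ended at 0 as the median SE rose from 0.08 to 0.14, and labelling batch and fetal exposure cannot be told apart. RNA integrity stays open, since 0 probe sets followed either measure of it: with the GAPDH ratio 0.962 ± 0.109 was kept (0.414 to 0.398, median SE 0.077 to 0.103, calls 0), and with the integrity number, added after the GAPDH test had decided nothing and the 166 calls of this fit were known, 1.19 ± 0.114 was (0.41 to 0.49); within groups the set fell as that number rose (16 arrays, r = -0.658, permutation p = 0.0162, adjusted p = 0.0324 over both measures, Spearman rho = -0.702, permutation p = 0.0117), opposite to what higher numbers after fetal DBP need, which counts against that number as the cause, but without the 2 arrays farthest from its median the relation kept its sign and missed the threshold (r = -0.512, permutation p = 0.0658). The GAPDH ratio itself also differed in part, with fetal DBP minus oil at -0.142 before postnatal oil (exact permutation test, two-sided, p = 0.0571). Before postnatal DBP it was -0.13 (exact p = 0.0857). RNA integrity by that measure therefore stays open. Exposure in utero and the litter of the pups may also account for the averaged difference, neither was tested apart, and the probe sets were chosen on the same arrays.

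On the GD20 array of dam 21 (DBP), all 75 probe sets that are above an intensity of 5000 at PND35 and below 100 in GD20 oil were above the GD20 oil mean. Their median excess was 2.4% of the PND35 level, 2.73% in the brighter and 2.33% in the dimmer part, against 0.145% with 52 of 75 higher for dam 19, the other DBP array of the low spike-in class. Tnp1 was at 843 against 98.6 ± 16.2 in oil, and Odf1, a sperm tail protein, at 825 against 65.1 ± 1.3. RNA of older testis on that array may account for this, as a hypothesis found on the same data. Early expression in fetal germ cells is not excluded, and no biological explanation was tested.

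Smpx (1.54 ± 0.16) and 3 further genes of striated muscle chosen after their values were seen, Myom2 (0.82 ± 0.11), Mybpc3 (0.76 ± 0.13) and Ldb3 (0.63 ± 0.11), rose at GD20 after fetal DBP. Muscle tissue in the DBP samples could raise them, but a separate list of 27 muscle genes had a median log2 fold change of 0.13 (median absolute deviation 0.23, 20 of 27 higher), below the change of the 4 genes by more than its spread. This argues against muscle tissue as the whole cause, with limits. The 4 genes were chosen on their values, and part of the list is dim, where the pseudocount shrinks changes. Ckm, abundant in muscle but dim here (60.6 against 27.4), was higher by 0.74 ± 0.43 (adjusted p = 0.541). A change of these genes within testis cells by fetal DBP stays open and was not tested apart.

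Other splits of the same arrays were run for each count of calls. At GD20 the real split gave 137 and the highest of the others 1, so 1 of 35 splits, the real one, gave as many. That is the smallest share these splits allow, so chance is made unlikely but not excluded. The other splits mix the groups, which adds any real difference to the spread and tends to lower their counts. After fetal oil 1 of 35 gave as many (2770), and the highest other, 2120, exchanges only pups 105 and 120 between the sides. After fetal DBP 1 of 35 did (1623 against at most 0). Chance is neither excluded nor made unlikely for the 1 call of fetal DBP before postnatal oil, where 2 of 35 splits gave as many and the highest other gave 1. For fetal DBP before postnatal DBP, with 0 calls, all 35 of 35 gave as many. No split can give fewer than 0, so that comparison decides nothing. The split of pups 105, 124, 128 and 135 from 111, 115, 121 and 133 gave 368, which points to a structure of the samples other than the groups. For the interaction, with 0 calls, 100 of 100 random groupings gave as many, which was likewise fixed beforehand. The highest gave 1719, which also points to the structure of the samples, since such groupings mix the postnatal exposures.

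A single array stood apart from the other 3 of its group in 15 of 366 groups looked at, where chance gives 18.3. The values are the gap to the nearest array over the range of the group. At GD20 they were 0.937 for the myoid list (oil, dam 2), 0.946 for the fatty acid synthesis list (DBP, dam 18), 0.925 for the spermatocyte list (DBP, dam 21), 0.917 for Ccnd2 (dam 18), 0.916 for Clu (dam 21), 0.843 for Cyp17a1 (dam 19) and 0.906 for Dennd6b (dam 19). At PND35 with fetal oil they were 0.933 for the NRF2 list (oil-oil, pup 114), 0.901 for Nfkbiz and 0.874 for Slc25a45 (oil-oil, pup 104) and 0.832 for S100a9 (oil-DBP, pup 115). With fetal DBP they were 0.867 for Atf3 and 0.931 for Icam1 (DBP-oil, pup 127), 0.925 for Tle6 (DBP-oil, pup 134) and 0.841 for Cxcl10 (DBP-DBP, pup 135).

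In 85 probe sets a test of the difference in the fetal DBP effect between the ages passed (GD20 minus PND35 before oil). The named genes among them were Stc1 (1.98), Smpx (1.79), Chchd4l1 (1.15), Mical3 (-1.42), Ccnd2 (-1.13) and Rcor1 (-1.07). This test takes both ages together, which the main fits keep apart. Median replicate spread was 0.144 (oil) and 0.254 (DBP) at GD20, and 0.229 (oil-oil) and 0.212 (DBP-oil) at PND35. The spike-in class also ran opposite ways. At GD20 2 DBP arrays were low and all oil arrays high, while 2 DBP-oil arrays were high and all oil-oil arrays low. An effect of DBP that depends on age therefore cannot be told apart from the class. The response to postnatal DBP differed by fetal exposure in the Sertoli marker list (median -0.15) and the spermatid list (median 0.19), with camera calls that are lost with an estimated correlation (adjusted p = 0.703 both).

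The manufacturer's controls, which the comparisons leave out, were averaged into 15 families and tested as such. Of these families 5 were higher in DBP-DBP than in oil-DBP, by a log2 fold change of 1.85 for Dap, 1.56 for Thr, 1.33 for Phe, 0.72 for Lys and 0.47 for the hexokinase control. Dap, Thr, Phe and Lys are the spike-ins that defined the class, so their differences restate it. The actin control was higher by 0.48 after postnatal DBP in animals with fetal oil.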

How the results depend on the processing

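The spike-in class, the GAPDH ratio, the averaged contrast, no centring at PND35 and leaving out arrays for the agreement and for the GD20 probe sets at PND35 were chosen after seeing the data. At GD20 the 137 calls became 210 without dim probe sets, 10 without the intensity trend, 42 without the pooled array and 29 to 175 without 1 array. After fetal oil the 2770 became 1508 with the RNA integrity number as a covariate, 1541 in the 8 arrays alone and 1597 to 4607 without 1 array. After fetal DBP the 1623 became 935 with the spike-in class and 874 in the high arrays, and 1097 to 1519 without 1 array. For fetal DBP before postnatal oil the 1 call became 0 without the intensity trend, with the extraction method, without the Trizol arrays, in the 8 arrays alone, with the spike-in class and in the low arrays, 14 with the RNA integrity number, and 0 to 14 without 1 array. For fetal DBP before postnatal DBP the 0 calls became 7 with quantile normalization or without dim probe sets, 1 with centring on the 75th percentile, without the trend or without the Trizol arrays, 16 with array weights, 63 with the RNA integrity number, 3 as deposited, and 0 to 35 without 1 array. The averaged fetal contrast, with 115, gave 205 without dim probe sets, 3 without the trend, 218 with array weights, 16 with the extraction method, 22 without the Trizol arrays, 0 with the GAPDH ratio or the spike-in class, and 31 to 188 without 1 array. The interaction stayed at 0 calls by limma under each alternative run (1466 at an unadjusted p under 0.05 in the fit reported).

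The agreement of the postnatal responses, r = 0.612, was 0.876 in brighter probe sets, 0.912 in those called in either, which were picked on the same changes, and 0.568 to 0.612 without 1 array. The same-sign share of GD20 probe sets at PND35, 45.255%, ranged from 32.432% to 49.635% without 1 array. The RNA integrity difference after fetal DBP, -0.025, ranged from -0.083 to 0.058 without 1 array. Of 26 lists past camera's threshold over the 6 contrasts, 13 were past it with an estimated correlation and 18 by fry. Those lost by fry were the spermatid (adjusted p = 0.506) and myoid (0.095) lists at GD20, the macrophage list after fetal oil (0.225), the spermatid list after fetal DBP (0.312) and before postnatal oil (0.717), the Sertoli list before postnatal DBP (0.91), and both lists of the interaction (0.567). Another 7 passed by fry alone: NRF2 at GD20 (adjusted p = 0.0179), heat shock after fetal DBP (0.0355) and, after fetal oil, steroidogenesis (0.0438), fatty acid synthesis (0.0305), PPAR (0.0254), spermatocyte (0.0438) and cell cycle (0.0438). Adjacent pup numbers were not taken as pairs, since only 4 of 8 correlations within them were over 0.1 (-0.13 to 0.25). Yet 8 of 16 arrays were closest to their own partner among 4 candidates each, which is more than chance gives. Pairing is therefore not ruled out. As a block, adjacent pup numbers gave 3114 and 1655 calls for postnatal DBP after fetal oil and after fetal DBP. For the named genes that passed, 0 changed direction under an alternative, and calls were lost in 149 of 470 combinations of gene and alternative at GD20, 192 of 1795 after fetal oil and 114 of 1507 after fetal DBP. Except where fewer arrays or probe sets were used, the cause was not tested. Signal over background limits dim genes, since 12.1% to 19.4% of probe sets per array lie below the pseudocount.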

Other observations

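The sets of genes and the spermatid tests below were chosen only after the data were seen, so they are values with no independent test.

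Among 6 genes of the NF-kB family and its regulators, 5 rose after postnatal DBP in animals with fetal oil and 6 in animals with fetal DBP. Nfkb2 rose by 3.15 ± 0.35 and 3.21 ± 0.35, Nfkb1 by 2.64 ± 0.19 and 2.20 ± 0.19, Bcl3 by 2.63 ± 0.32 and 3.57 ± 0.32, Relb by 1.79 ± 0.16 and 1.64 ± 0.16, and Tnip1 by 1.26 ± 0.16 and 1.16 ± 0.16, while Birc3 was at 0.36 ± 0.12 (adjusted p = 0.0609) and 0.50 ± 0.12 (adjusted p = 0.012). Of 10 growth factors and members of the activin axis 4 rose in each: Fst, Inhba, the activin A subunit (2.48 ± 0.53 and 2.56 ± 0.53), Bmp2 (1.95 ± 0.31 and 1.35 ± 0.31) and Vegfa (1.33 ± 0.24 and 1.09 ± 0.24). Areg, Ereg, Lif, Il11, Hbegf and Fgf2 did not pass. Of 8 genes of the matrix and the plasminogen system 4 passed in each: Plaur, the urokinase receptor (3.73 ± 0.35 and 3.53 ± 0.35), Adamts1 (2.45 ± 0.22 and 3.22 ± 0.22) and Timp1 (1.74 ± 0.20 and 1.93 ± 0.20) rose, while Plau, urokinase itself, fell (-1.11 ± 0.18 and -0.90 ± 0.18). Has2, Ptgs2, Mmp3 and Thbd did not pass.

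The mean of the spermatid list was lower after postnatal DBP by 0.37 ± 0.16 in animals with fetal oil and by 0.17 ± 0.10 in animals with fetal DBP (exact permutation test within both strata, two-sided, p = 0.0171, with 24 lists looked at). In each alone the exact p was 0.0857 and 0.114. With fetal oil the difference was -0.30 as deposited, -0.36 with centring on the 75th percentile and -0.23 with quantile normalization.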
